A study of Mus musculus with 6 samples.

How the data were processed

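Bulk RNA sequencing was done on the prefrontal cortex of 6 mice, 3 per group, with no sorting of cells, per the labels. The control group carried CamKIIα-Cre without the floxed allele. The Gls1_CamKIIaCre group carried CamKIIα-Cre with a single floxed allele, so that Cre, made in excitatory forebrain neurons, removes that allele in part of the cells. Controls were littermates, per the series description. Total RNA was extracted with TRIzol and made into libraries with a SMARTer mRNA-Seq kit, per the labels' protocols. The genome build was GRCm38 (mm10), per the submitters' processing notes. The aligner, the counting tool, the use of strand and the tool that made the FPKM values are not given in the sources used here.

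The authors deposited whole-number read counts per gene, and a second table of the same 21878 genes and the same libraries in FPKM (fragments scaled for gene length and library size), which was used only as an alternative input. Per the file headers, each gene also has an NCBI gene identifier, GO terms and KEGG pathways. Gene names were taken as deposited. Without strand, reads of overlapping genes cannot be told apart. This applies to Gls2, Zbed6, Kcnh7, Srrm2, Grin1, Lrrtm2, Nr1d1, Ifit3b, Ifi27, Cxcl10, Tagln, Ddit3, Ctsz, Zbtb16, Hspa5 and Rpl23a, whose spans overlap another protein-coding gene. Values of genes with near-identical copies (the haemoglobins, C4b, Ifit3b and the ribosomal proteins) depend on how shared reads were counted. Of the rows, 21727 matched an NCBI gene of the GRCm38.p6 RefSeq table, which gave the coordinates, and 27 symbols stored as calendar dates were restored through their identifiers. The table holds no row for the genes encoded in mitochondrial DNA among the fixed lists, nor for Xist, Tsix and Mx1. Every library carried Y-linked transcripts, with Ddx3y between 77.6 and 95.3 CPM, so no term for sex was fitted. The deposited tables give no gene type. The RefSeq table gives one, which was used to leave out pseudogenes and to find overlapping protein-coding genes. An analysis of protein-coding genes apart from others was not run.

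Library totals lay between 17987807 and 19330961 counts. Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, the filterByExpr filter and the robust quasi-likelihood fit (glmQLFit and glmQLFTest), with Gls1_CamKIIaCre set against control and no covariate. The filter left 14440 genes. Values per library are TMM-normalised CPM (counts scaled to library size). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and fold changes are Gls1_CamKIIaCre over control. The common biological coefficient of variation was 4.75%. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom between 2.36 and 4.46, so none was a duplicate of another. The labels call the samples separate mice.

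Of 44 gene lists written before the data were examined, covering pathways, cell types, neighbouring brain regions and RNA quality, 42 had at least 5 tested members and entered limma's camera test (limma 3.58.1) with a preset correlation between genes of 0.01. Annotation terms with 15 to 500 tested genes entered the same test. Both were adjusted by Benjamini-Hochberg over the lists or over the terms. Each list is also described by how many members passed over all genes tested, and how many passed when adjusted over the list alone. Medians of a list are over its tested members. Named genes followed a rule written before the data were examined: Gls2, Camk2a, Glul and Slc17a7, then the 12 genes of smallest p in each direction among those called, at a mean of 1 CPM or more and without unnamed gene models, pseudogenes or sex-linked genes, and for each list described up to 4 members of smallest p and every called member where these were 6 or fewer. Some genes that the rule picks are not reported here.

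Alternatives were DESeq2 1.42.0, limma voom, DESeq2 size factors or upper-quartile factors in edgeR, no filter on low counts, a mean of 50 counts or more, the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a non-robust fit, other thresholds, camera with an estimated correlation, fry, and leaving out each library in turn. Chosen after the data were seen were a correction for transcript length and GC content, a covariate for striatal transcripts, and the removal of striatum members from other lists. The correction used a smooth fit per library with 4 degrees of freedom for each property, taken from the longest GENCODE M21 transcript of a gene, which was found for 98.8% of tested genes. The covariate was the mean over the striatum list of each gene's CPM relative to its mean over the 6 libraries.

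The procedure was tested on simulated counts of the 14440 genes for the comparison of Gls1_CamKIIaCre with control. It recovered 51.4% of genes changed by 1.2-fold, 88.9% of those changed by 1.5-fold and 100% of those changed by 2-fold, and called 8 of 14220 unchanged genes. The changed genes were drawn from those with a mean of 50 counts or more, so recovery at lower counts was not tested. The camera step called the raised list and 0 of 41 unchanged lists. Simulated genes varied independently of each other, so that result does not cover lists whose genes vary together. The striatum list, for example, had an estimated correlation of 0.79. With a simulated length trend, unchanged genes called went from 109 to 11 after the correction, which recovered 79% of changed genes.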

Results

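The expression of 21878 genes was measured by bulk RNA sequencing in prefrontal cortex from 3 control mice and 3 Gls1_CamKIIaCre mice. The comparison asks how the cortical transcriptome differs when 1 floxed allele is lost in part of the CamKIIα-Cre neurons. Control libraries held 19330961, 18997592 and 18665024 counts, and Gls1_CamKIIaCre libraries 18644314, 17987807 and 19265382. The first principal component, with 39.3% of the variance, separated the groups.

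Among genes set for description beforehand, Gls2, Glul, Slc17a7 and Camk2a did not pass by edgeR. Gls2, a gene of glutamine breakdown, stood at 20.4 ± 1.34 CPM in control against 20.1 ± 0.615 CPM in Gls1_CamKIIaCre (SD, n = 3 per group, edgeR adjusted p = 0.927), and Glul, the glutamine synthetase of astrocytes, at 1732 ± 42.6 against 1697 ± 46.1 CPM (0.715). Slc17a7, the main vesicular glutamate transporter of cortex, had 1453 ± 153 against 1433 ± 56.8 CPM (0.910). Camk2a, whose promoter drives the Cre, had 3256 ± 58.3 against 3562 ± 187 CPM (0.0602), and it passed with DESeq2 (adjusted p = 0.0273), limma voom (0.0301), no filter on low counts (0.0277) and a replicate block (0.00928), and without Gls1_CamKIIaCre 1 (0.048).

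**Figure D1:**
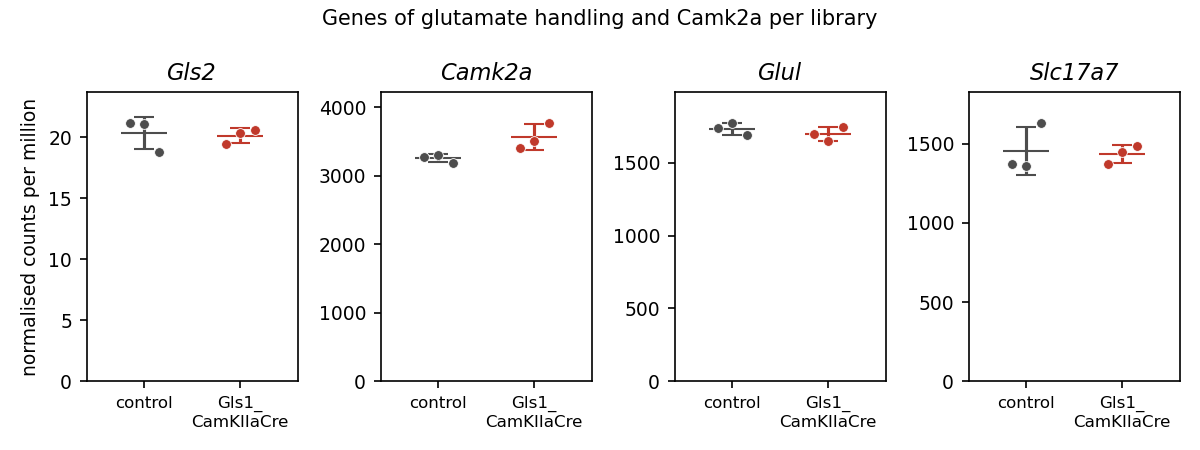
Normalised CPM of Gls2, Camk2a, Glul and Slc17a7 in each library, with points for the 3 libraries of a group and bars for the mean and SD. None of the 4 genes passed the edgeR test, and Camk2a, of smallest p, has means of 3256 and 3562 CPM.

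The mutant cortex differed from control at 1190 of 14440 genes, of which 571 were higher and 619 lower. Most differences were small, with a median absolute log2 fold change of 0.23 among called genes. Large ones lay on the lower side: 140 genes fell by 1.5-fold or more and 75 by 2-fold or more, against 24 and 7 that rose as far. The gene lists of lowest median were markers of the striatum and interferon-induced genes. The share of calls that were higher was 48.0%, against 36.4% with upper-quartile factors (429 higher, 749 lower), 17.2% on log2(FPKM + 1) (116 higher, 558 lower) and 16.7% on log2(FPKM + 0.1) (122 higher, 607 lower). The FPKM values lie lower in the mutants as a whole, with sums per library of 238924 to 243144 against 249602 to 252272 in the controls. Leaving out a library moved the count to 415 without Gls1_CamKIIaCre 2, 635 without control 2, 763 without control 1 and 778 without Gls1_CamKIIaCre 1.

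**Figure D2:**
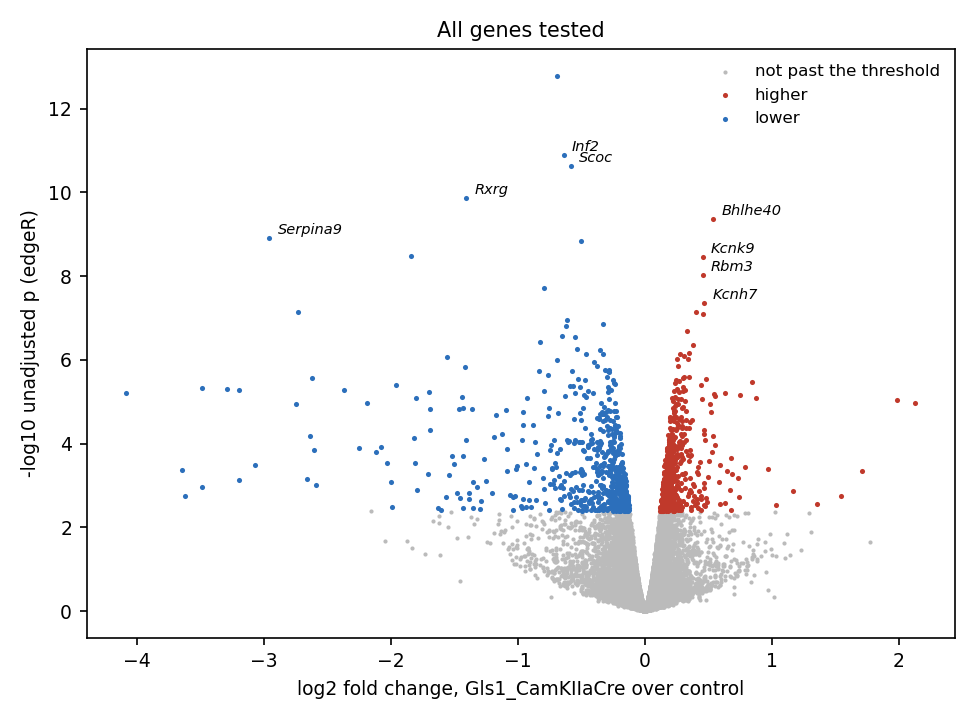
Log2 fold change of Gls1_CamKIIaCre over control against -log10 of the unadjusted edgeR p for each of the 14440 genes tested, with the 571 called higher in red, the 619 called lower in blue and the others in grey. Genes with large fold changes lie mostly on the lower side.

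The higher genes of smallest p were led by Bhlhe40, a transcriptional repressor of the circadian clock, which rose from 98.1 ± 6.68 to 142 ± 4.29 CPM (SD, n = 3 per group, log2 fold change 0.54 ± 0.049 SE, edgeR adjusted p = 1.26e-06). Kcnk9, a leak potassium channel, rose by a log2 fold change of 0.46 ± 0.047 (SE), and Rbm3, a cold-inducible RNA-binding protein, from 76.5 ± 4.57 to 105 ± 3.08 CPM. Kcnh7, a voltage-gated potassium channel, rose by 0.47 ± 0.054, and Scn2a1, a voltage-gated sodium channel, by 0.28 ± 0.040. The others were Lnpep, an aminopeptidase, at 0.40, Zbed6 at 0.46, Srrm2, a splicing factor, at 0.34, Palm2 at 0.38, Ncam2, a cell adhesion molecule, at 0.35, Chka, a choline kinase, at 0.31, and Rasgrf1, an activator of Ras, at 0.25. Adjusted p of these 12 genes lay between 1.26e-06 and 0.000423 by edgeR. Zbed6 lies inside Zc3h11a, and reads of the host gene could be counted there.

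Lower genes of small p included Inf2, a formin that acts on actin, which fell from 134 to 86.1 CPM (log2 fold change -0.64 ± 0.048 SE, edgeR adjusted p = 9.5e-08), and Scoc, a Golgi coiled-coil protein, from 168 to 112 CPM (-0.58 ± 0.045, adjusted p = 1.12e-07). Rxrg, a retinoid X receptor, fell from 15.2 to 5.71 CPM. Ptpn5, which encodes the striatal-enriched phosphatase STEP, fell from 189 to 133 CPM, Ecel1, an endopeptidase-like gene, from 7.71 to 2.14 CPM, and Nts, the neurotensin precursor, from 2.89 to 0.430 CPM. Foxp2 had a log2 fold change of -0.61, Foxo1 of -0.62 and Kcnj10, the inward-rectifier potassium channel of glia, of -0.33. Serpina9 and Strip2, also among them, belong to the striatum list. The edgeR adjusted p of these 11 genes lay between 9.5e-08 and 0.000122.

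All 20 tested striatum markers were lower in the mutant samples, by a median log2 fold change of -1.61, and 17 of them passed over all genes (20 adjusted over the list alone). Serpina9 fell from 5.22 to 0.669 CPM, Gpr6, a receptor of striatopallidal neurons, from 8.44 to 1.37 CPM, Isl1, a transcription factor of striatonigral neurons, from 1.87 to 0.198 CPM, and Strip2 from 94.3 to 54.5 CPM. The list's camera test gave an adjusted p of 5.52e-35 (adjusted p = 0.217 with an estimated correlation). The mean level of the list, relative to each gene's mean over all libraries, was 1.17, 2.08 and 1.41 in the controls and 0.425, 0.426 and 0.486 in the mutants, so controls also differed among themselves. The hippocampus list (median -0.14, 1 higher and 3 lower of 14, the same adjusted over the list alone, camera adjusted p = 0.0904), the olfactory bulb list (-0.094, 0 and 1 of 14, 0.225) and the thalamus and hypothalamus list (-0.11, 0 and 0 of 9 by edgeR, as by DESeq2, limma voom or an unadjusted p under 0.05, 0.497) did not pass. The hippocampus list passed at a mean of 50 counts or more (camera adjusted p = 0.047) and without control 3 (0.0285, median -0.25), and its median was -0.072 without control 2. The olfactory bulb list passed without control 3 (0.00784, median -0.19), without Gls1_CamKIIaCre 1 (0.00264, -0.29) and with the striatum level as a covariate (0.00779, -0.47), while its median turned to 0.18 without control 1 and 0.16 without Gls1_CamKIIaCre 3, and was -0.15 without Gls1_CamKIIaCre 2 and -0.027 after the length and GC correction. The thalamus and hypothalamus median ranged from -0.18 without Gls1_CamKIIaCre 1 to -0.049 without control 2. On the hippocampus list, Wfs1, Man1a and Calb1 fell and Bok rose, and Uchl1 was the lower gene of the olfactory bulb list. With the striatum level as a covariate, which correlated with group at -0.898 over the 6 libraries, the comparison called 41 genes, 35 of them among the 1190. That covariate moved the medians of the interferon list to -2.02, the neuropeptide list to -0.41, the meningeal list to -0.29, the reactive astrocyte list to -0.25 and the disease-associated microglia list to -0.18, with their calls kept. Because the covariate nearly overlaps the groups, a call kept or lost under it does not decide whether striatal tissue contributes. Among the controls, the interferon level was highest in control 1, where the striatum level was lowest.

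**Figure D3:**
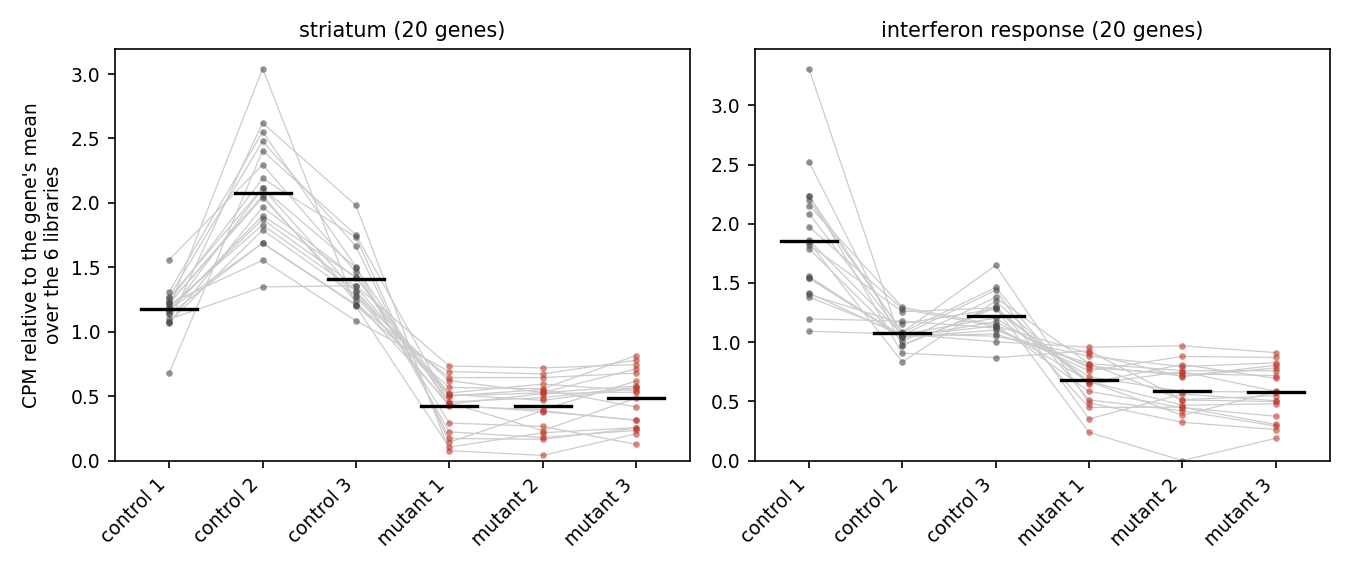
CPM of each gene relative to its mean over the 6 libraries, for the 20 striatum markers and the 20 interferon response genes tested, with a point per gene and library, a grey line per gene and a black bar for the mean of the list. The striatum mean is highest in control 2 at 2.08 and the interferon mean in control 1 at 1.86, and both lists lie lowest in the mutant libraries.

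Interferon-induced genes were lower in the mutants as a group, with a median log2 fold change of -1.08. Of 20 tested, 13 fell and none rose over all genes (20 fell adjusted over the list alone). Bst2, an antiviral membrane protein, went from 5.95 to 2.22 CPM, Isg15, a ubiquitin-like modifier, from 3.16 to 0.811 CPM, Ifit3b from 11.1 to 6.24 CPM and Ifi27 from 24.2 to 17.4 CPM. The camera adjusted p was 2.79e-20 (adjusted p = 0.275 with an estimated correlation). The level was highest in control 1, at 1.86 against 1.07 and 1.22 in the other controls and 0.578 to 0.681 in the mutants, and without control 1 the median was -0.81.

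Several complement genes were also lower: C1qa, C1qb, C1qc and C4b fell, by log2 fold changes of -0.33, -0.48, -0.35 and -0.68, while Mertk, a phagocytic receptor, rose by 0.31. These were the 5 called among 19 complement and phagocytosis genes (2 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0218). That call had an adjusted p = 0.277 with an estimated correlation, and it was lost without Gls1_CamKIIaCre 2 (camera adjusted p = 0.0905). The complement median was -0.21, and -0.13 without control 1, -0.12 without Gls1_CamKIIaCre 2 and -0.10 without Gls1_CamKIIaCre 3. Genes induced in disease-associated microglia had a median of -0.12, and Ctsz, Cd9, Lyz2 and Lpl were the 4 of 17 that fell (4 adjusted over the list alone). Their camera adjusted p was 0.00124 (adjusted p = 0.217 with an estimated correlation). Microglia markers had a median of -0.12, and 2 of 20, Olfml3 and Ctss, fell (2 adjusted over the list alone), with a camera adjusted p of 0.0215 (adjusted p = 0.286 with an estimated correlation), which was 0.106 without control 1, 0.0907 without Gls1_CamKIIaCre 2, where the median was -0.066, and 0.0714 after the correction for transcript length and GC content, where the median was -0.070. Of 15 cytokine and NF-kB response genes, 0 passed by edgeR, DESeq2 or limma voom, 0 adjusted over the list alone and 2 at an unadjusted edgeR p under 0.05 (camera adjusted p = 0.81), and Nfkbia, of smallest p, had 13.8 against 16.7 CPM.

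Markers of several non-neuronal cell types were lower. Oligodendrocyte markers had a median of -0.26, and 10 of 18 fell (13 adjusted over the list alone), among them Trf at -0.40, Mag at -0.33, Fa2h at -0.37 and Ppp1r14a at -0.60. The camera adjusted p was 4.22e-11 (adjusted p = 0.275 with an estimated correlation). With the striatum level as a covariate the oligodendrocyte median was 0.061 (camera adjusted p = 0.685). Meningeal and fibroblast markers had a median of -0.50, and 9 of 15 fell (13 adjusted over the list alone), including the matrix genes Fmod at -0.53, Col1a2 at -0.51 and Dcn at -0.40 and the collagen-processing gene Pcolce at -0.76, with a camera adjusted p of 2.51e-09 (adjusted p = 0.275 with an estimated correlation). Of 22 endothelial and mural markers, 8 fell and none rose (10 and 1 adjusted over the list alone), with a median of -0.24. Tagln stood at -0.72, Pdgfrb at -0.35, Cldn5 at -0.33 and Vtn at -0.28. The list had a camera adjusted p of 1.58e-05 (adjusted p = 0.275 with an estimated correlation), and 0.598 with the striatum level as a covariate, where the median was -0.12.

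Astrocyte markers were lower by a smaller amount, with a median of -0.12. Gjb6, Gja1, S100b and Aldoc were the 4 of 19 that fell (10 lower and 1 higher adjusted over the list alone), and the camera adjusted p was 0.000167 (adjusted p = 0.217 with an estimated correlation), or 0.066 with the striatum level as a covariate, where the median was -0.072. On the reactive astrocyte list, Serpina3n, C4b, Cxcl10, Vim and Aspg fell, while Lcn2, a secreted iron-binding protein, rose from 0.452 to 2 CPM. These were 5 lower and 1 higher of 16 (6 and 1 adjusted over the list alone), with a median of -0.15 and a camera adjusted p of 0.00273 (adjusted p = 0.275 with an estimated correlation). That median was -0.27 without Gls1_CamKIIaCre 1 and -0.25 at a mean of 50 counts or more. Cxcl10, like the interferon list, was highest in control 1 (3.73, 1.10 and 1.45 CPM in the controls), and it was near the floor in the mutants (0.268, 0 and 0.211 CPM). Oligodendrocyte precursor markers Cacng4, Olig2 and Olig1 fell, 3 of 13 (3 adjusted over the list alone), with a median of -0.16 and a camera adjusted p of 0.0137 (adjusted p = 0.275 with an estimated correlation), which was 0.0635 without Gls1_CamKIIaCre 1, with a median of -0.067, and 0.223 with the striatum level as a covariate, where the median kept most of its size at -0.14. The haemoglobin genes Hbb-bs and Hba-a2 fell, 2 of 8 blood genes (2 adjusted over the list alone), with a median of -0.23 and a camera adjusted p of 0.00777 (adjusted p = 0.286 with an estimated correlation). The blood median was -0.13 without control 2, -0.37 without Gls1_CamKIIaCre 1 and -0.14 without Gls1_CamKIIaCre 2. Its p was 0.0597 without Gls1_CamKIIaCre 2, 0.098 after the length and GC correction, with a median of -0.097, and 0.598 with the striatum covariate, with a median of -0.036. Of 10 choroid plexus and ependyma genes, 0 passed by edgeR, DESeq2 or limma voom, 0 adjusted over the list alone and 3 at an unadjusted edgeR p under 0.05, with a median of -0.43 (camera adjusted p = 0.0855, and 0.0473 after the length and GC correction), which was -0.017 with the striatum covariate.

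Several immediate early genes, which neuronal activity induces, rose. Of 26 tested, 7 rose and 1 fell (10 and 2 adjusted over the list alone), with a median log2 fold change of 0.40. Nr4a3 rose from 18.5 to 34 CPM (0.87 ± 0.114 SE, edgeR adjusted p = 0.00123), Egr4 from 15.2 to 22.4 CPM and Btg2 from 19.3 to 26.8 CPM, whereas Nptx2, a secreted pentraxin that binds AMPA receptors, fell from 52.9 to 30.6 CPM. The camera adjusted p of the list was 9.5e-07 (adjusted p = 0.286 with an estimated correlation), and 0.124 with the striatum level as a covariate, where the median was 0.29. Without Gls1_CamKIIaCre 2 the median was 0.25.

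Of 16 circadian clock genes 4 passed the threshold, and Bhlhe40, Nr1d1, Per1 and Cry2 rose (5 higher and 1 lower adjusted over the list alone). Per1, which neuronal activity and glucocorticoids also induce, rose from 62.7 to 89.4 CPM. The list's median was 0.076 and its camera adjusted p 0.00919 (adjusted p = 0.275 with an estimated correlation), which was 0.0599 without Gls1_CamKIIaCre 3, with a median of 0.030, and the median was 0.037 without control 1. Of 18 glucocorticoid response genes, Per1, Zbtb16 and Ddit4 rose and Mt2 fell (7 higher and 1 lower adjusted over the list alone), with a median of 0.13 and a camera adjusted p of 0.00467 (adjusted p = 0.275 with an estimated correlation).

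Some glutamate receptor and postsynaptic genes rose by small amounts. On the ionotropic glutamate receptor list, the NMDA receptor subunits Grin2b, Grin2a and Grin1 rose, by log2 fold changes of 0.47, 0.33 and 0.18, and the AMPA receptor subunits Gria3 and Gria2 by 0.21 and 0.13, while Neto2, an auxiliary subunit of kainate receptors, fell by 0.29 on the log2 scale. These 6 were the called members among 24 (5 higher and 2 lower adjusted over the list alone), and the list did not pass the camera test (adjusted p = 0.0848, median 0.027), though it did without control 3 (0.0151, median 0.045), and its median was 0.0064 after the length and GC correction. Homer2 and Grm2 rose, 2 of 10 metabotropic glutamate receptor genes (3 adjusted over the list alone, camera adjusted p = 0.0874, and 0.0438 without Gls1_CamKIIaCre 3). Postsynaptic density genes Dlgap1, Kalrn, Iqsec2 and Lrrtm2 rose, 4 of 25 (7 higher and 1 lower adjusted over the list alone), with a median of 0.075 and a camera adjusted p of 0.00467 (adjusted p = 0.325 with an estimated correlation), which was 0.0594 without control 1, 0.0556 without Gls1_CamKIIaCre 3 and 0.194 after the length and GC correction, with medians of 0.056, 0.088 and 0.055. The uncorrected median lay at the 97.4th percentile of lists matched on transcript length and expression (matched median 0.035), near the upper end of their spread.

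Of 26 synaptic vesicle genes 5 rose, Dnm1, Pclo, Stx1a and Rims1 among them, and Sv2c fell (8 higher and 1 lower adjusted over the list alone), with a median of 0.051 and a camera adjusted p of 0.00375 (adjusted p = 0.447 with an estimated correlation). That p was 0.067 without Gls1_CamKIIaCre 3 and 0.162 with the striatum covariate, where the median was 0.021, and the median was 0.087 after the length and GC correction. The uncorrected median lay at the 88.8th percentile of lists matched on transcript length and expression (matched median 0.029), inside the spread of those lists. The correction raised the median instead of lowering it, so the matched lists and the correction differ on how much the length trend contributes. Genes linked to autism, many of them synaptic or chromatin genes, had a median of 0.083: 10 of 40 rose and 1 fell (14 and 1 adjusted over the list alone), with Scn2a1 at 0.28, Grin2b at 0.47 and the single lower gene Foxp2 at -0.61. The camera adjusted p was 8.01e-07 (adjusted p = 0.275 with an estimated correlation). After the length and GC correction the median was 0.047 and the camera adjusted p 0.0327, still under 0.05. The uncorrected median lay at the 87.1th percentile of lists matched on transcript length and expression (matched median 0.065), inside the spread of those lists. Voltage-gated channels Kcnh7, Scn2a1, Scn8a and Cacna1b rose, 4 of 32 (7 higher and 3 lower adjusted over the list alone), with a median of 0.063 and a camera adjusted p of 0.0333 (adjusted p = 0.325 with an estimated correlation). For that list the adjusted p was 0.144 without control 1, 0.0643 without control 2, 0.0599 without Gls1_CamKIIaCre 3, 0.741 after the length and GC correction, with a median of -0.00090, and 0.066 with the striatum covariate, with a median of 0.039.

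Some genes of GABA handling were lower. Gad2, which makes GABA from glutamate, fell from 301 to 243 CPM (log2 fold change -0.31 ± 0.047 SE, edgeR adjusted p = 0.000631), and Abat and Slc32a1, of GABA breakdown and vesicular loading, fell by log2 fold changes of -0.18 and -0.23. They were the 3 called of 9 GABA synthesis and transport genes (3 adjusted over the list alone), with a median of -0.089 and a camera adjusted p of 0.0137 (adjusted p = 0.325 with an estimated correlation). The adjusted p was 0.0732 without control 2, 0.1 without Gls1_CamKIIaCre 3 and 0.785 with the striatum level as a covariate, where the median was -0.0083, and the median was -0.15 without control 3, -0.18 without Gls1_CamKIIaCre 1 and -0.058 without Gls1_CamKIIaCre 3. On the interneuron list, Gad2, Sst, Npy, Slc32a1 and Tac1 fell and Erbb4 rose, 6 of 25 (1 higher and 5 lower adjusted over the list alone). Tac1, like the striatum list, was highest in control 2 (35.3, 59.4 and 35.7 CPM in the controls). The interneuron list did not pass (camera adjusted p = 0.125, median -0.089). It passed without control 3 (0.0409) and without Gls1_CamKIIaCre 1 (0.0263, median -0.12), and its median was 0.0059 without control 1, 0.021 without Gls1_CamKIIaCre 3 and -0.048 after the length and GC correction. Of 17 GABA receptor genes only Gabra3 rose over all genes (1 adjusted over the list alone), at 0.14, and the camera adjusted p was 0.0665, under 0.05 without control 2 (0.0441), control 3 (0.0118) or Gls1_CamKIIaCre 1 (0.0406) and with the striatum covariate (0.0229). Neuropeptide genes were lower, with 7 of 19 called (7 adjusted over the list alone): Nts, Sst at -0.25, Pdyn at -0.85 and Cartpt at -0.91 had the smallest p. The list's median was -0.18 and its camera adjusted p 9.61e-05 (adjusted p = 0.217 with an estimated correlation). Without its 3 members shared with the striatum list the neuropeptide median was -0.14 (camera adjusted p = 0.0216), and with all members it was -0.11 after the length and GC correction.

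Markers of deep cortical layers were lower, with a median of -0.20. Of 18, 5 fell and 2 rose (8 and 2 adjusted over the list alone), and the smallest p belonged to Foxp2 at -0.61, Pcp4 at -0.28, Sulf1 at -0.36 and Hs3st4 at -0.27. The camera adjusted p was 0.00124 (adjusted p = 0.275 with an estimated correlation), and 0.384 with the striatum level as a covariate, where the median was -0.052. Upper-layer markers did not pass (camera adjusted p = 0.459, median -0.0047, which turned to 0.021 without control 3 and 0.026 without Gls1_CamKIIaCre 3), though Rasgrf2 and Otof rose and Wfs1 fell, 3 of 14 (3 higher and 1 lower adjusted over the list alone). Among 29 monoamine and acetylcholine receptor genes, Drd2, also a striatum marker that was highest in control 2 (13.9, 27.0 and 15.9 CPM in the controls), fell from 18.9 to 2.24 CPM, a call lost with limma voom and without any 1 of the mutant libraries. Chrm3 rose from 62.4 to 72.7 CPM, a call lost without control 1, control 2, Gls1_CamKIIaCre 2 or Gls1_CamKIIaCre 3 (6 higher and 4 lower adjusted over the list alone, list camera adjusted p = 0.464, and 0.0846 without the members shared with the striatum list).

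Few genes of glutamate handling, glycolysis and the tricarboxylic acid cycle passed the test. Of 27 glutamine and glutamate metabolism genes, Bcat1, a branched-chain aminotransferase, was the one that rose, from 112 to 123 CPM (1 higher adjusted over the list alone), and the camera adjusted p was 0.856. Asns had a log2 fold change of 0.16 and Glud1 of -0.11, neither past the threshold (edgeR adjusted p = 0.0675 and 0.0768). Slc25a12, the mitochondrial aspartate-glutamate carrier of neurons, was the gene called among 21 glutamate and glutamine transporters (2 higher adjusted over the list alone), at 149 against 173 CPM (edgeR adjusted p = 0.00414, list camera adjusted p = 0.0874). The glucose transporter Slc2a1 rose at 0.22, the only call among 20 glycolysis genes (1 adjusted over the list alone, camera adjusted p = 0.225, and 0.0158 without control 3 and 0.0124 after the length and GC correction, with the list higher). Of 29 tricarboxylic acid cycle genes, 0 passed by edgeR, DESeq2 or limma voom, 0 adjusted over the list alone and 3 at an unadjusted edgeR p under 0.05 (camera adjusted p = 0.101). In the amino acid and integrated stress response list, Ddit3 and Nupr1 fell and Ddit4 and Slc3a2 rose, 4 of 22 (3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.295). Of 18 heat shock genes Hspa5 fell, at -0.21 (1 adjusted over the list alone, camera adjusted p = 0.81).

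Ribosomal protein and respiratory chain transcripts were lower by about the same small amount. Of 74 cytosolic ribosomal protein genes 23 fell and none rose (46 adjusted over the list alone), with a median of -0.13 and Rpl23a at -0.24, Rps21 at -0.24 and Rplp1 at -0.19. The camera adjusted p was 4.53e-18 (adjusted p = 0.277 with an estimated correlation). Of 39 nuclear-encoded oxidative phosphorylation genes 11 fell (17 adjusted over the list alone), with a median of -0.11 and Ndufa8 at -0.21, Ndufs4 at -0.25, Cox6a1 at -0.16 and Cox6c at -0.16, and a camera adjusted p of 2.97e-07 (adjusted p = 0.217 with an estimated correlation). Both calls ended after the correction for transcript length and GC content, with medians of -0.013 (camera adjusted p = 0.0578) and 0.018 (0.945). Antioxidant genes Prdx6, Srxn1, Prdx3 and Sod1 fell by log2 fold changes of -0.28, -0.25, -0.22 and -0.16, and 7 of 23 glutathione and oxidative stress genes were lower (8 adjusted over the list alone), with a median of -0.12 and a camera adjusted p of 0.000167 (adjusted p = 0.275 with an estimated correlation). That median was -0.078 without Gls1_CamKIIaCre 2 and -0.041 after the length and GC correction (camera adjusted p = 0.0135).

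**Figure D4:**
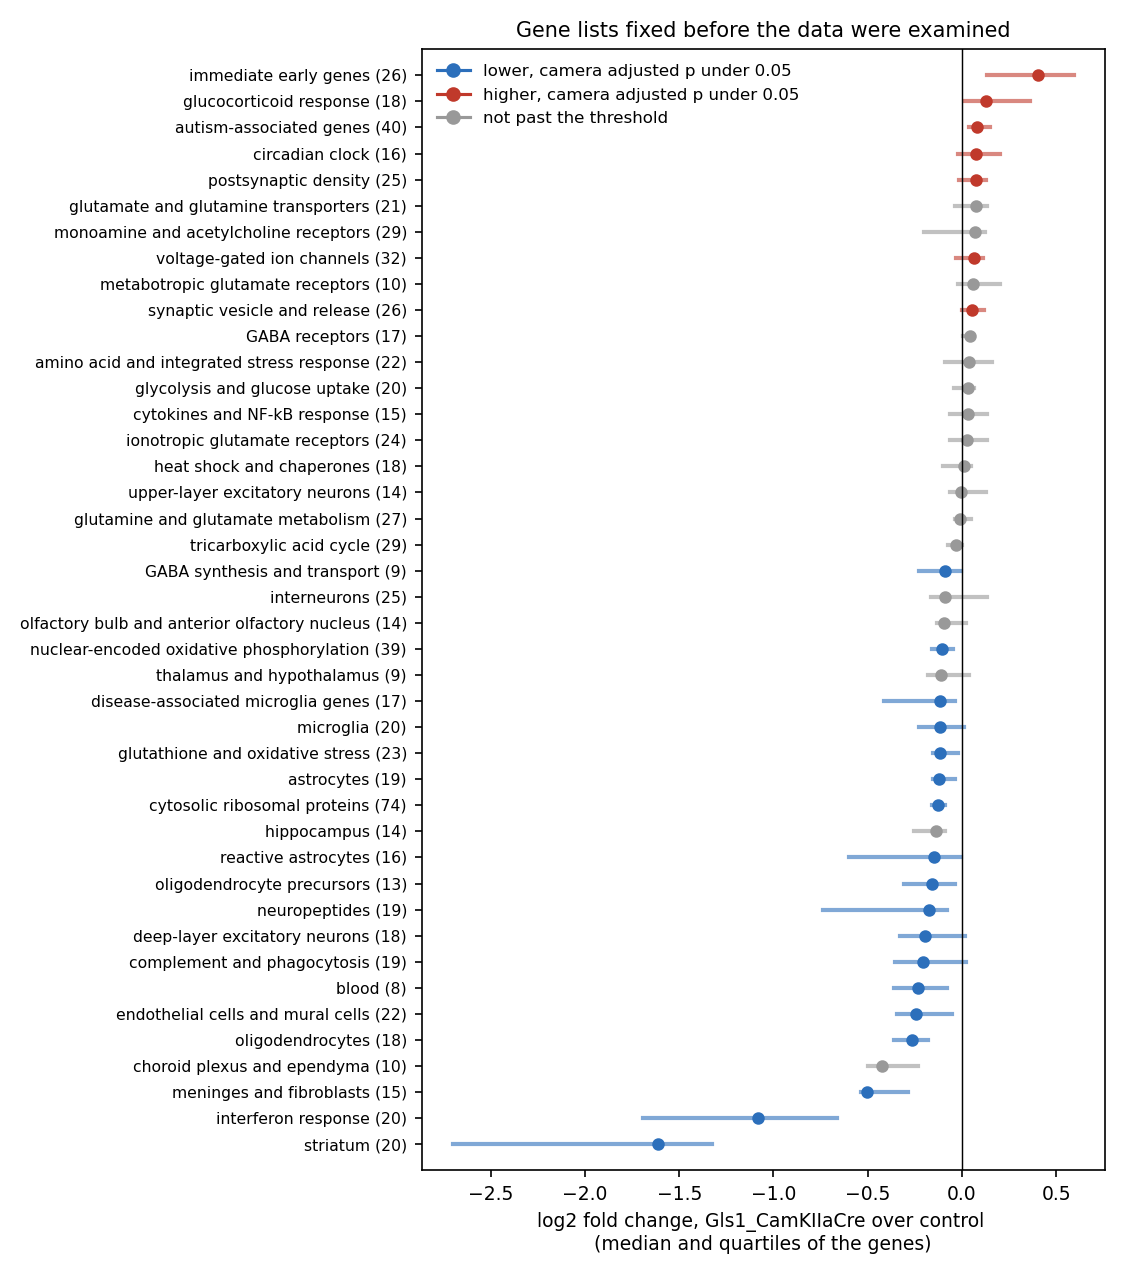
Median and quartiles of the log2 fold change, Gls1_CamKIIaCre over control, for the 42 gene lists tested, with the number of tested genes in parentheses and colour for the camera call at a preset correlation. Striatum and interferon lists lie lowest at -1.61 and -1.08, and immediate early genes highest at 0.40.

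In all, 25 of the 42 lists passed camera with the preset correlation, 7 higher and 18 lower. With an estimated correlation camera called 0, with a smallest adjusted p of 0.217 and 7 lists at an unadjusted p under 0.05. The fry test called 14, of which 12 were among the 25. It lost 13 calls, among them immediate early genes (fry adjusted p = 0.139), oligodendrocyte markers (0.0818) and ribosomal protein genes (0.0742). It also called the choroid plexus and ependyma list and the glutamate and glutamine transporter list (fry adjusted p = 0.0397 for each). Of 2475 annotation terms 114 passed, 44 higher and 70 lower, led by ribosome terms on the lower side (KEGG ribosome, 129 genes, median -0.12, camera adjusted p = 1.69e-13). With an estimated correlation camera called 0 terms, with a smallest adjusted p of 0.72 and 127 terms at an unadjusted p under 0.05, and fry called 87.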

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

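The corrections for transcript length and GC content, for striatal transcripts and for shared list members were chosen after the data were seen, and the other alternatives were set before the data were examined. No gene called in both the reported comparison and an alternative changed direction. The number of genes called was 914 with DESeq2, 1097 with limma voom, 1180 with DESeq2 size factors in edgeR, 1178 with upper-quartile factors, 1392 without a filter, 1171 at a mean of 50 counts or more and 1022 with a non-robust fit. It was 674 on log2(FPKM + 1), of which 116 higher, and 729 on log2(FPKM + 0.1), of which 122 higher. An adjusted p under 0.1 gave 1862 genes, 898 higher and 964 lower, and a fold of 1.5 or more gave 164, 24 higher and 140 lower. The FPKM values call fewer genes, and the median log2 fold change over all genes was -0.023 on log2(FPKM + 1) and -0.0312 on log2(FPKM + 0.1), so part of the lower share of higher calls may lie in their scale, which was not tested. Leaving out a library gave 415 (without Gls1_CamKIIaCre 2) to 1098 genes (without control 3), with 197 to 556 higher and 218 to 542 lower, 21 to 31 lists and 74 (without Gls1_CamKIIaCre 2) to 125 terms, from fewer samples. The uncalled genes Gls2 and Slc17a7 changed sign there: Gls2 ranged from -0.0709 (without control 3) to 0.0108 (without control 1) and Slc17a7 from -0.0628 (without control 2) to 0.0718 (without control 3).

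The length and GC correction called 858 genes, 725 of them among the 1190, with 493 higher and 365 lower, and 37 terms. Gls2 (0.0217), Glul (0.008) and Slc17a7 (0.0096) changed sign without being called, as did the medians of the voltage-gated channel list (-0.0009) and the oxidative phosphorylation list (0.0182). The striatum covariate called 41 genes, 3 higher and 38 lower, and 68 terms. Its near overlap with the groups leaves little to estimate the group effect from. Gls2 (0.0382), Glul (0.0295), Hbb-bs (0.0285) and the oligodendrocyte median (0.0614) changed sign. With an estimated correlation camera called 0 lists and 0 terms, while fry called 14 lists, 12 of them among the 25, and 87 terms. A replicate block called 1758 genes, 863 higher and 895 lower, including 1185 of the 1190, and it ended no list call. Same-numbered libraries deviated together at r = 0.139, -0.026 and 0.14. Controls 1 and 3 correlated best with their own number and control 2 did not. The labels do not say what the number stands for, so whether same-numbered samples are linked is not settled. A total of 148 single genes was followed through the alternatives, except for 5 genes that fall below the filter at a mean of 50 counts or more, with 11 sign changes, all in the genes given here, 13 calls gained and 498 lost, 131 of them under the striatum covariate. Of 139 called genes chosen by the naming rule, 63 lost the call without at least 1 library, and 0 of the 24 of smallest p did by edgeR. At this depth 51.4% of simulated 1.2-fold changes were recovered, in genes with a mean of 50 counts or more, so smaller differences can go uncalled. Other splits of the 6 libraries called at most 14 genes, 24 lists and 71 terms, against 1190, 25 and 114. The split of controls 1 and 2 with Gls1_CamKIIaCre 1 gave the 24 lists. For each count, 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. The sex and protein-coding alternatives were not run.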

Other observations

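Chosen only after the results were seen were the tests of control 2 against the other controls and of the length correction on the striatum list, and of microglia and exposure for the interferon list. For the striatum list, a correlation of CPM differences was run first (Pearson r = 0.9805) and then replaced by one of log2 ratios, with its cutoff set before its value was seen, because the most abundant genes dominate CPM differences. Control 2 also entered both sides of the first correlation, so a positive r was partly built in and its value is no support.

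Beyond the fixed lists, higher annotation terms included ones of chromatin and synapse formation. Long transcripts were higher as a whole, with a median log2 fold change of 0.049 among the 2854 genes of longest transcripts. The higher terms were not set against lists matched on length, and after the length and GC correction 37 terms passed in place of 114. Methylated histone binding (49 genes, median log2 fold change 0.066, camera adjusted p = 0.00366), chromatin organization (280 genes, 0.052, 0.00374), synapse assembly (63 genes, 0.10, 0.00381) and the axon initial segment (15 genes, 0.095, 0.00582) were higher. On the lower side, genes of peptide antigen binding, mostly histocompatibility molecules, had a median of -0.69 (17 genes, camera adjusted p = 9.17e-05), the cellular response to interferon-beta a median of -0.81 (30 genes, 6.78e-10) and peroxidase activity a median of -0.18 (23 genes, 0.000289). Each of these terms had an adjusted p = 0.72 with an estimated correlation.

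The striatum list was lower in every mutant library, and its most abundant members, Ppp1r1b, Pde10a and Gng7, fell from 243 to 81.7, from 238 to 87.1 and from 222 to 108 CPM. A transcript length and GC trend was argued against, since the list's median was -1.54 after the correction. A smaller share of striatal tissue in the mutant dissections may account for it. All 20 genes were also higher in control 2 than in controls 1 and 3, by 1.10-fold to 2.55-fold. Control 2 was chosen because the list's mean was highest there, so that count was partly set by the choice. Across genes, which are not independent replicates, the log2 ratio of control 2 to the other controls went with the ratio of those controls to the mutants (Pearson r = 0.532). Cortical neurons express several list members too, and an effect of the genotype on these genes stays open and untested. For the 602 other lower genes, the median log2 excess of control 2 was 0.0275, between the values that would argue for or against the same source. It was 0.1055 in the 123 of these genes that fell by 1.5-fold or more, with 68 (55.3%) above 0. In the 479 that fell by less it was 0.0274, with 292 (61.0%) above 0, and 49.9% of all genes tested were above 0. The share above 0 was thus not larger among the larger falls. Over whole lists, whether or not a member was called, the median excess was 0.168 for oligodendrocyte markers (18 of 18 above 0), 0.1008 for meningeal markers (12 of 15) and -0.3467 for interferon genes (2 of 20).

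Short transcripts were lower and long ones higher: among the 2854 genes of shortest transcripts 217 were called lower and 21 higher, among the 2854 of longest transcripts 85 and 275. Ribosomal protein and oxidative phosphorylation genes, with median transcript lengths of 942 and 1005 bases, are consistent with that trend. The ribosomal protein median of -0.13 lay at the 37.3th percentile of 10000 lists matched on transcript length and expression, whose median was -0.12, and the correction moved it to -0.013. Control 2 exceeded the other controls by a median of only 0.00361 on the log2 scale in these genes, which does not decide whether striatal tissue contributes. RNA quality and library preparation, like a genotype effect on long neuronal genes, cannot be told apart as the origin of the trend, because it follows the groups. The slope against length was taken on each library's deviation from the gene's mean over the 6 libraries, so its sign is relative to the other libraries. This slope was negative in all 3 controls (-0.135 to -0.0438 log2 CPM per 10-fold length) and positive in all 3 mutants (0.056 to 0.0974).

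The interferon list fell in all 3 mutant libraries. Fewer microglia were argued against, since microglia markers lay 0.967 above the interferon genes in median log2 fold change. An exposure, cage or litter that differed between the groups cannot be told apart from the genotype, since controls described as littermates need not be balanced over litters and cages. For 19 of 20 genes every control lay above every mutant library. The genes vary together (estimated correlation 0.69), so that count cannot be set against a chance share per gene.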
